A study of Mus musculus with 6 samples.

How the data were processed

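Whole retinas of female DBA/2J mice were assayed on Affymetrix mouse arrays, 1 retina per array and 3 arrays per age. Per the labels' protocols, retinas were rinsed to remove blood, total RNA was extracted on columns, and 20 ng of each sample was amplified and biotin-labelled with a NuGEN kit. Separate animal numbers in the labels show that the replicates are separate mice. The deposited values are on the log2 scale, per probe set, and were made with GCRMA 1.1.0 in R 1.9.0, per the submitters' processing notes. As a method, GCRMA models background from probe sequence and presses weak signals toward a floor, so differences of dim genes can be understated. The options used in it, scan dates and detection calls were not given in the sources used here. The quantitative PCR on other retinas that the design mentions was not analysed here.

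The table held 45101 probe sets, of which 64 Affymetrix controls were left out. A probe set was kept where the third highest of the 6 values reached 4 on the log2 scale, without regard to age, which kept 20973, or 46.6%. Genes were named from the platform annotation, in which 34945 probe sets had 1 gene, 932 had several and 9160 had none listed. Of the probe sets with 1 gene, 34741 matched the gene table of GRCm38.p6 by gene identifier and 204 did not, and 0 symbols changed. Each gene was represented by its kept probe set of highest mean over the 6 arrays, giving 11219 genes, of which 4574 had more than 1 kept probe set. Among kept probe sets, 2916 carried the suffix _s_at or _x_at, which marks probes that can match several transcripts.

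Ages were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all kept probe sets, a threshold of 0.05 and two-sided tests. No covariate entered the model. Shifts of gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists tested, with fry and camera with an estimated correlation beside it. Of 40 lists, 35 had the minimum of 5 measured genes. They cover the retinal cell types, glia and immune pathways, stress and metabolic pathways, and other tissues that a retina sample can hold. Of the listed symbols, 2 were not found in the annotation. The grouping, the lists, the tests, the named-gene rule and all alternatives except those on lens material were set before the data were examined. Camera with its preset correlation called 7 lists, and with an estimated correlation it called 0, the smallest adjusted p being 0.155. The estimate was 0.006 for gliosis, -0.117 for complement and -0.015 for cell cycle, all below the preset. A larger correlation therefore did not end those calls. The estimate was 0.021 for microglia, 0.055 for interferon, 0.113 for class I and 0.420 for heat shock. Fry called 4, of which microglia and complement were also called by camera.

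The named genes were the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping ages. Where fewer passed in a direction, the genes of smallest unadjusted p filled up to 5. Up to 4 members of smallest p were taken from each list, with a fixed set of markers of gliosis, ganglion cells, pigment, complement, iron transport and microglia, of which some are not reported here. Fold changes are ratios back-transformed from log2 differences, and SD and SE refer to log2 values.

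The number of arrays limits the precision. An exact permutation test of 3 against 3 cannot give a two-sided p under 0.1, so single values were not tested that way. The models were tested on 5 simulated sets of 20973 probe sets with 200 changed in each. The share recovered was 12.8% at a log2 difference of 0.5, 80.6% at 1 and 99.4% at 2, and 29 unchanged probe sets were called over the 5 sets. The adjusted threshold loosens as more probe sets change. Each simulated set held 200 changed ones, whereas the real comparison called 1, with 30 differing by 2-fold or more. The shares recovered are therefore not those to be had in the real comparison. A list of 15 genes raised by 0.4 was called in 5 of 5 sets by camera and in 4 with an estimated correlation, and 2 of 195 unchanged lists were called. Each probe set was simulated independently, so these lists held no correlation between genes. The 2 of 195 is therefore not a rate of false calls for the real lists.

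RNA quality was read from control probe sets as the 3' minus 5' log2 signal. It was 1.76 ± 0.13 and 1.79 ± 0.07 for actin and 0.73 ± 0.02 and 0.78 ± 0.03 for Gapdh at 3 and 8 months (SD, n = 3). The Gapdh values of the ages did not overlap, at 0.707 to 0.751 and 0.755 to 0.811, while those of actin did. Correlations of arrays across probe sets lay between 0.987 and 0.994 within an age and between 0.985 and 0.994 across ages. Eye side overlaps with age, since right eyes occur only at 8 months, so no comparison of ages within right eyes was possible, and left eyes hold 1 older retina.

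The alternatives were no filter and a filter at 6, quantile, median and cyclic loess normalization, an intensity trend with a robust prior, array weights, replicate number as a block and eye side as a covariate. Further ones were only specific probe sets, the mean of a gene's probe sets, other thresholds, other list tests and each array left out in turn. Added after seeing the data were the crystallin mean of each array as a covariate and a fit without the 2 arrays richest in crystallin.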

Results

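Messenger RNA was measured in whole retinas of female DBA/2J mice, an inbred strain that develops glaucoma with age and serves as a model of the disease. The question was which retinal genes differ between animals with normal intraocular pressure at 3 months and animals with elevated pressure at 8 months. Each of 6 Affymetrix arrays held 1 retina, 3 per age, from separate animals. The last pressure measured in the sampled eyes was 17.5 ± 1.99 mmHg at 3 months and 27.4 ± 2.67 mmHg at 8 months (SD, n = 3 each). Animals were chosen by pressure, so age and pressure differed together. All 3-month retinas came from left eyes, whereas 8-month retina 1 came from a left eye and 8-month retinas 2 and 3 from right eyes. The share of probe sets at or above 4 on the log2 scale lay between 46.1% and 46.6% in every array.

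Lens crystallins, the structural proteins of the lens fibre cells, varied more between single retinas than between ages. Their mean log2 level was 9.27 in 8-month retina 1 and 10.41 in 3-month retina 3, against 4.69 and 5.06 in the other 8-month retinas and 6.49 and 5.09 in the other 3-month retinas. Cryba1, a beta-crystallin, read 12.53 in 8-month retina 1 and 13.53 in 3-month retina 3, and between 3.93 and 8.90 in the rest. The crystallin list did not pass between ages, with a mean log2 difference of -0.99 over 10 genes (limma camera, Benjamini-Hochberg adjusted p = 0.649). It passed as lower without 8-month retina 1 (limma camera, adjusted p = 0.0211) and as higher with eye side as a covariate (0.0213).

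**Figure D1:**
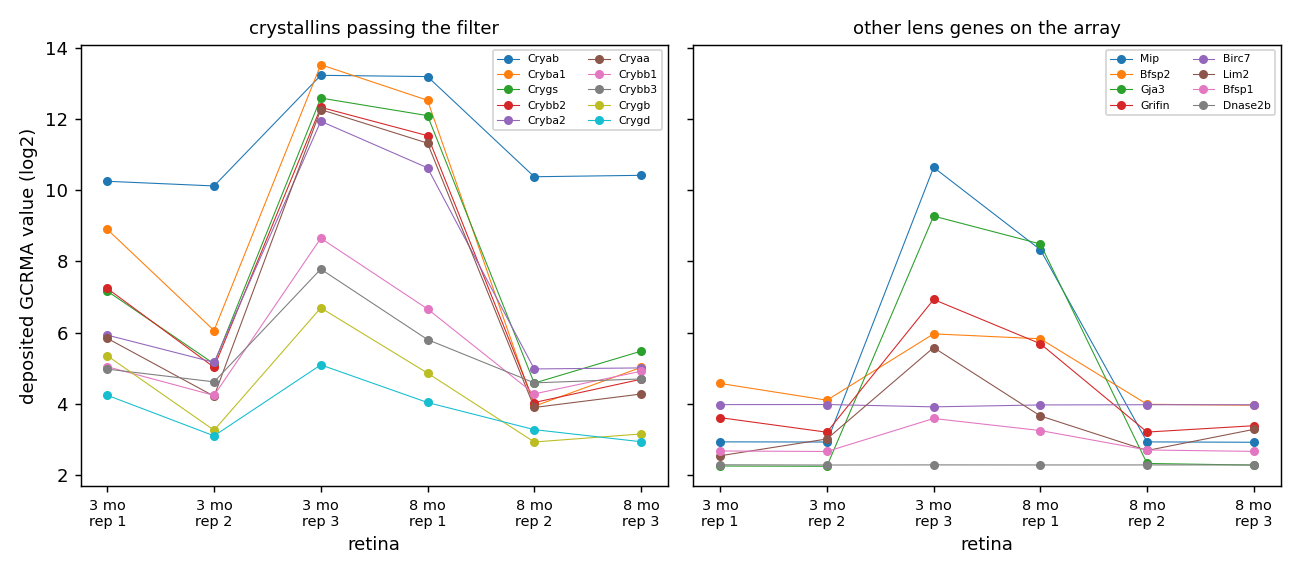
Deposited log2 values (y axis) of the crystallins that passed the filter on low values (left) and of other lens genes on the array (right) in each of the 6 retinas (x axis); each line joins the values of 1 gene. Most of the genes stand highest in 3-month retina 3 and 8-month retina 1, for example Cryba1 at 13.53 and 12.53.

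Glb1l3, a gene of the beta-galactosidase family, was the 1 gene that passed the test over all probe sets. Its log2 level was 7.70 ± 0.19 at 8 months and 5.65 ± 0.15 at 3 months (SD, n = 3 each), a 4.14-fold rise with all 3 older retinas above all 3 younger ones (limma, Benjamini-Hochberg adjusted p = 0.0149). Csrp3, which encodes a muscle LIM-domain protein, was 2.20-fold higher at 8 months and missed the threshold (limma adjusted p = 0.0935). The next smallest p values among higher genes belonged to the mitotic checkpoint kinase gene Bub1b, the adaptor gene Skap2 and B2m, the light chain of class I molecules, with log2 differences of 0.97 ± 0.12, 0.82 ± 0.10 and 0.62 ± 0.08 (SE). Among lower genes, Fam53b, Zfp286, Nsmce3, Malsu1 and Gm36839 had the smallest p values, with log2 differences from -0.66 for Fam53b to -0.54 for Nsmce3. Those 8 genes shared a limma adjusted p of 0.177, none passing, although each had its 3 older retinas on one side of its 3 younger ones. A further probe set of Fam53b differed by 0.05, and Zfp286, Nsmce3 and Gm36839 lay below 4.5 at both ages, close to the filter. The call of Glb1l3 was lost when any single array was left out, with limma adjusted p between 0.0694 and 0.164 and log2 differences between 1.94 and 2.12. It was also lost with eye side as a covariate (limma adjusted p = 0.416).

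Beyond Glb1l3, single-gene differences were small and numerous. At an unadjusted limma p under 0.05 there were 3126 of 20973 probe sets, or 14.9%, where 1049 are given by chance. Of these, 971 were higher and 2155 lower at 8 months. That balance followed the scaling of the arrays, being 1385 higher and 1410 lower after quantile normalization, 1446 and 1386 after cyclic loess, and 787 and 2556 after median centring. The count was 2061 without 8-month retina 1, 1932 without 8-month retina 2, 2059 with eye side as a covariate, and 1567 without both crystallin-rich retinas, a choice made after seeing the data. In 4575 probe sets, 21.8%, the ranges of the ages did not overlap, against 10% by chance. The difference reached 2-fold in 30 probe sets, 20 higher and 10 lower.

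Genes of microglia and macrophages, the resident and infiltrating phagocytes, were higher at 8 months. Over 15 measured members the mean log2 difference was 0.38, with 14 members higher (limma camera, Benjamini-Hochberg adjusted p = 2.39e-06; adjusted p = 0.155 with an estimated correlation). Adjusted over the list alone, 4 members passed and all 4 rose, against 0 over all genes. Lyz1 and Lyz2, the lysozyme genes, rose from 4.17 ± 0.26 to 5.58 ± 0.46 and from 3.97 ± 0.21 to 4.71 ± 0.31 (log2, SD, n = 3). Their transcripts are close copies of each other, so the probe sets may not tell them apart. The lysosomal protease gene Ctss rose from 8.34 ± 0.07 to 8.99 ± 0.18, and Tyrobp, a signalling adaptor of myeloid receptors, from 4.39 ± 0.11 to 4.74 ± 0.10. Aif1, another microglial marker, stayed below the filter, with readings from 2.62 to 3.03.

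The complement list moved the same way, with a mean log2 difference of 0.51 and all 5 measured members higher (limma camera, adjusted p = 3.85e-04; adjusted p = 0.155 with an estimated correlation). C1qb, a chain of the initiating C1q complex, and Cd59a, an inhibitor of the terminal membrane attack complex, passed when adjusted over the list alone, 2 genes against 0 over all genes. C1qb rose from 7.01 ± 0.04 to 8.05 ± 0.37 and Cd59a from 7.80 ± 0.20 to 8.23 ± 0.15 (log2, SD, n = 3). A further Cd59a probe set, dimmer at 4.82 and 4.92, differed by 0.10 with overlapping ages (limma unadjusted p = 0.388). The C1qb value comes from a less specific probe set, 1 whose probes may match other transcripts, as does a further difference of 0.77, and its 1 specific probe set, near the filter at 4.71 and 4.81, differed by 0.10 with overlapping ages (limma unadjusted p = 0.296). C2 and Serping1 had log2 differences of 0.52 ± 0.21 and 0.45 ± 0.31 (SE), neither passing, and C1qa lay below the filter. C2 was also read by a less specific probe set, close to the filter. It stood at 3.39, 4.27 and 3.63 in the 3-month retinas and at 4.36, 4.26 and 4.23 in the 8-month ones. Only 5 of the 22 listed complement genes were measured.

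In the class I antigen presentation list B2m rose from 9.03 ± 0.06 to 9.65 ± 0.08 (log2, SD, n = 3). It was the 1 of 8 members to pass adjusted over the list alone, against 0 over all genes. The list's mean log2 difference was 0.14 with 5 members higher (limma camera, adjusted p = 0.0274; adjusted p = 0.412 with an estimated correlation). Among the others, H2-K1, Calr and Pdia3 had log2 differences of 0.26, 0.18 and 0.26, while a further Pdia3 probe set differed by -0.18. The class I call was lost without 3-month retina 2 (limma camera adjusted p = 0.216), without 8-month retina 2 (0.120), with eye side as a covariate (0.260) and without the less specific probe sets (0.0533). The class II list had 4 measured members, too few for the list test. Its H2-Aa rose from 4.05 ± 0.16 to 4.58 ± 0.11, passing adjusted over the list alone but not over all genes, while Cd74, H2-Ab1 and H2-DMa differed by 0.17, 0.16 and -0.15 (log2).

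The list of astrocyte and gliosis genes, which mark reactive glia, had a mean log2 difference of 0.38 over 20 genes, 17 of them higher at 8 months (limma camera, adjusted p = 7.38e-05; adjusted p = 0.155 with an estimated correlation). S1pr3, a sphingosine-1-phosphate receptor gene, rose from 7.31 ± 0.20 to 8.02 ± 0.22 and was the 1 member to pass adjusted over the list alone, against 0 over all genes. Gfap, the intermediate filament of reactive astrocytes and Müller cells, read 4.41 ± 0.27 and 5.48 ± 0.53 at 3 and 8 months and did not pass. Osmr, the oncostatin M receptor gene, and Socs3, a feedback inhibitor of cytokine signalling, differed by 0.44 ± 0.13 and 0.64 ± 0.22 (log2, SE). Ceruloplasmin, Cp, differed by 0.76 ± 0.27 with overlapping ages, and the iron-siderophore carrier Lcn2 by 2.01 ± 0.88. The 7 Cp probe sets were all higher, by 0.02 to 0.84, but those at 0.02 and 0.04 were almost level. Lcn2 differed strongly among the older retinas, at 5.23 in 8-month retina 1 against 8.97 and 8.19 in the other two, and between 5.03 and 5.87 at 3 months. Gfap was likewise lowest in that retina among the older ones, at 4.87, as was Cp in 5 of its 7 probe sets, at 8.64 in the brightest. The call was lost when the filter was raised to 6 (limma camera adjusted p = 0.0848), as was that of microglia (0.0523).

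**Figure D2:**
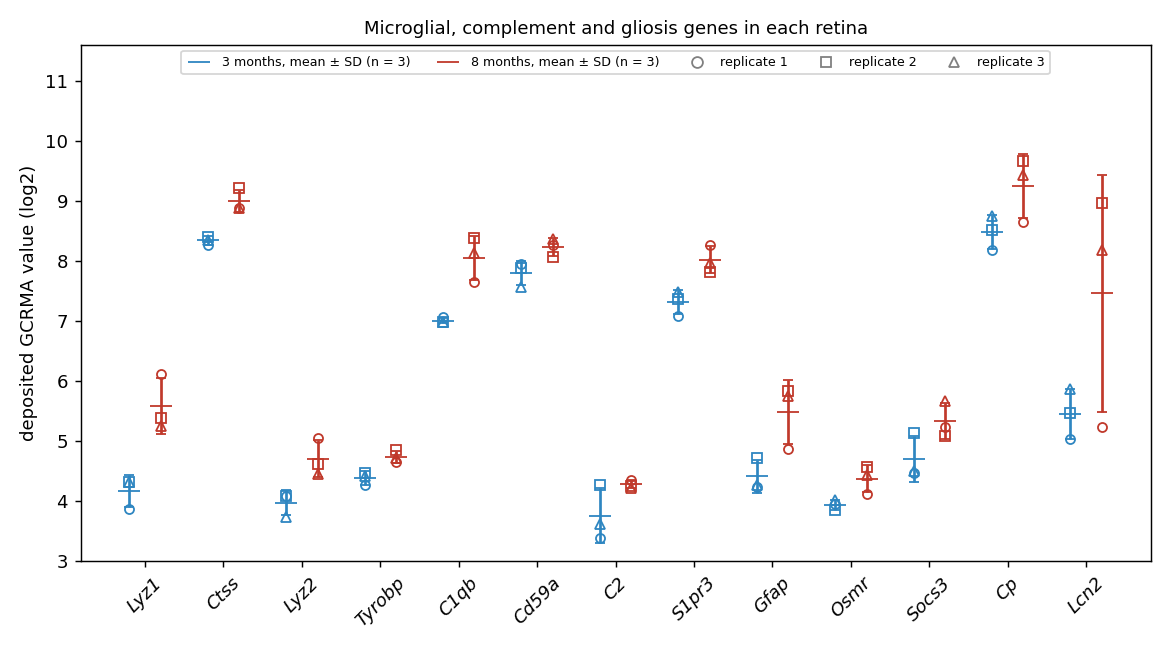
Deposited log2 values (y axis) of microglial (Lyz1 to Tyrobp), complement (C1qb to C2) and gliosis genes (S1pr3 to Lcn2) on the x axis, at 3 months (blue) and 8 months (red); symbols are single retinas, long ticks are means and bars are SD (n = 3). Lcn2 in 8-month retina 1 lies at 5.23, apart from 8.97 and 8.19 in the other 8-month retinas.

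Interferon response genes had a mean log2 difference of 0.25 but a median of 0.07 over 13 genes, 11 of them higher (limma camera, adjusted p = 0.00261, and 0.333 with an estimated correlation). No member passed, whether adjusted over the list alone or over all genes. Ifitm3, an antiviral membrane protein gene, read 6.58 ± 0.33 at 3 months and 7.82 ± 0.82 at 8 months, with 6.90 in 8-month retina 1 against 8.48 and 8.06 in the others. Ifi27, Irf9 and Ifi35 had log2 differences of 0.46, 0.39 and 0.31. With eye side as a covariate the list's call was lost (limma camera adjusted p = 0.134).

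Heat shock and unfolded protein response genes had a mean log2 difference of 0.11 over 18 genes, 13 of them higher (limma camera, adjusted p = 6.79e-04; adjusted p = 0.520 with an estimated correlation). The list means of the ages overlapped. Against the 3-month mean they were 0.045, 0.119 and 0.169 in 8-month retinas 1 to 3, and 0.073, 0.049 and -0.122 in 3-month retinas 1 to 3. The chaperone genes Hspa1b, Hsp90aa1 and Hspa8 and the co-chaperone gene Dnajb9 differed by 0.33, 0.33, 0.20 and 0.26 (log2), and 0 members passed adjusted over the list alone or over all genes. The cell cycle list had a mean log2 difference of 0.13 over 11 genes, 7 of them higher (limma camera, adjusted p = 0.0353; adjusted p = 0.333 with an estimated correlation). Its D-type cyclin genes Ccnd2 and Ccnd1, the cyclin gene Ccne1 and the ribonucleotide reductase gene Rrm2 differed by 0.46, 0.46, 0.24 and 0.24 (log2), with 0 members passing adjusted over the list alone or over all genes. Over all kept probe sets the difference ranged from 0.08 to 0.46 for Ccnd2 (5) and from 0.07 to 0.46 for Ccnd1 (3). Of 2 Ccne1 probe sets, 1 differed by -0.03. The Ccnd1 value was highest in the crystallin-rich retinas, at 8.09 in 8-month retina 1 and 7.70 in 3-month retina 3. With eye side as a covariate the limma camera adjusted p was 0.144 for heat shock and 0.260 for cell cycle, both calls lost. The cell cycle call was also lost after quantile normalization (0.0655), after cyclic loess (0.0845) and without 3-month retina 1, 3-month retina 2, 8-month retina 2 or 8-month retina 3 (0.0677, 0.150, 0.106 and 0.0557).

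Markers of retinal ganglion cells, the neurons lost in glaucoma, had a mean log2 difference of -0.11 over 24 genes, 18 of them lower, and the list did not pass (limma camera, adjusted p = 0.328). Tubb3, a neuronal beta-tubulin gene, fell from 6.64 ± 0.20 to 6.06 ± 0.10 (log2, SD, n = 3), the 1 member passing adjusted over the list alone, against 0 over all genes. The ganglion cell transcription factor gene Pou4f1 read 9.86 ± 0.12 and 9.61 ± 0.08 at 3 and 8 months, Thy1 9.15 ± 0.14 and 9.03 ± 0.18, and the light neurofilament gene Nefl 11.03 ± 0.14 and 10.90 ± 0.07, none passing. Neurofilament and axonal cytoskeleton genes, which include Tubb3, had a mean of -0.12 over 19 genes, with Kif1a at -0.27 and Ank3 at -0.30 (limma camera, adjusted p = 0.337), and Tubb3 alone passed adjusted over the list alone.

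Genes of axon injury and growth had a mean log2 difference of -0.16 over 14 genes, 11 of them lower. They did not pass against other genes (limma camera, adjusted p = 0.211), but did in limma's fry, which asks whether a list's genes move one way on balance (adjusted p = 0.0476). Sox11, a transcription factor gene of growing neurons, fell from 7.83 ± 0.06 to 7.30 ± 0.17, and Marcksl1, an actin regulator, from 8.48 ± 0.13 to 8.03 ± 0.15 (log2, SD, n = 3). These 2 passed adjusted over the list alone, against 0 over all genes, and 1 of 4 Marcksl1 probe sets was higher at 8 months. Endothelial and pericyte genes also passed in fry alone, with a mean of -0.20 over 10 genes (limma camera, adjusted p = 0.337; fry, adjusted p = 0.0476). The efflux transporter gene Abcb1a fell from 6.11 ± 0.15 to 5.45 ± 0.15, the 1 member passing adjusted over the list alone, against 0 over all genes. Cldn5, a tight junction gene, and Tek, an angiopoietin receptor gene, differed by -0.44 and -0.57.

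Rod genes had a mean log2 difference of -0.10 over 19 genes, 14 of them lower, and did not pass (limma camera, adjusted p = 0.337). Prph2 and Rom1, partners in the rim of the outer segment disc, differed by -0.53 ± 0.16 and -0.19 ± 0.07 (SE), Pde6b by -0.20 and Grk1 by -0.36. Of 10 cone genes, 3 fell and passed adjusted over the list alone, against 0 over all genes: Gnat2, the cone transducin, by 0.44, the medium-wavelength opsin Opn1mw by 0.48 and the channel subunit Kcne2 by 0.49 on the log2 scale. Pde6c, a cone phosphodiesterase, was 0.34 higher without passing, and the cone list did not pass (mean -0.13; limma camera, adjusted p = 0.373). Mitochondrial respiratory chain genes were lower in 22 of 26 and cytosolic ribosomal protein genes in 18 of 22, with means of -0.09 and -0.07, and neither list passed (limma camera, adjusted p = 0.211 and 0.373). Both passed as lower with no filter on low values (limma camera, adjusted p = 0.00688 and 0.0366). The median log2 difference of all probe sets tested was -0.041 with the filter and -7.96e-04 without it. The lists were thus set against a different background there.

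Müller glia genes had a mean log2 difference of 0.08 over 18 genes, with the water channel gene Aqp4 at 0.31 and glutamine synthetase, Glul, at 0.15 (limma camera, adjusted p = 0.132; 0.0397 without 3-month retina 3). Bipolar, amacrine and horizontal cell lists had means of -0.01, -0.02 and -0.02 (limma camera, adjusted p = 0.337, 0.197 and 0.662), with Pax6 at 0.23, Tfap2b at 0.26 and Vip at -0.49 among amacrine genes. Neurotrophic factors and receptors came nearest to the threshold, at a mean of 0.09 (limma camera, adjusted p = 0.0697, and 0.0279 without 8-month retina 1), with the GDNF-family co-receptor genes Gfra1 and Gfra2 at 0.35 and 0.33 and Vegfa at 0.53. Further probe sets of Gfra2 and Vegfa differed by as little as 0.03 and 0.05. In the apoptosis list, which did not pass (mean -0.09; limma camera, adjusted p = 0.529), the survival gene Bcl2 rose from 6.01 ± 0.09 to 6.48 ± 0.15, the 1 of 13 members passing adjusted over the list alone, against 0 over all genes. Common reference genes had a mean of 0.08 (limma camera, adjusted p = 0.129; 0.0294 with eye side as a covariate), and B2m was again the 1 member passing adjusted over the list alone, against 0 over all genes. In the lists of crystallins, rods, Müller glia, bipolar, amacrine and horizontal cells, neurotrophic factors, respiratory chain and ribosomal proteins, 0 members passed adjusted over the list alone or over all genes.

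The remaining lists did not pass with all arrays, and no member passed adjusted over the list alone or over all genes. Limma camera adjusted p values were 0.132 for hypoxia and glycolysis (mean log2 difference 0.09; limma camera adjusted p = 0.00535 without 8-month retina 2), 0.164 for glutamate and GABA receptors (0.05), 0.211 for the circadian clock (0.03) and 0.219 for pigment epithelium and visual cycle (0.12). They were 0.387 for iris and ciliary tissue (0.09), 0.462 for extracellular matrix (-0.05), 0.481 for both immediate early genes and cytokines, and 0.547 for synaptic transmission (-0.02). For iron and oxidative stress (-0.02), cholesterol synthesis (-0.06) and voltage-gated channels (-0.06) they were 0.827, 0.827 and 0.968. Dlg4, a postsynaptic scaffold gene, differed by -0.51, Dusp1, a phosphatase gene induced by stress, by 0.35, and Gadd45a by -0.36. Lists of pigment cells, blood cells, oligodendrocytes and other lens genes had 3, 4, 3 and 1 measured members and were not tested as lists. Tyrp1, which carries a pigment mutation in this strain, read 5.95 ± 0.997 and 5.55 ± 0.997 at 3 and 8 months, and Gpnmb, which carries the other, lay below the filter. Haemoglobin Hbb-b2 read 8.13 ± 1.16 and 7.87 ± 0.76, and the myelin gene Mbp 6.98 ± 0.15 and 7.04 ± 0.04 (log2, SD, n = 3). In 10 lists, none of them called, the sign of the camera test differed from that of the mean or of the median. The mean itself changed sign with another scaling in 7 of these, namely amacrine, bipolar and horizontal cells, immediate early genes, cytokines, synaptic transmission and iron.

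**Figure D3:**
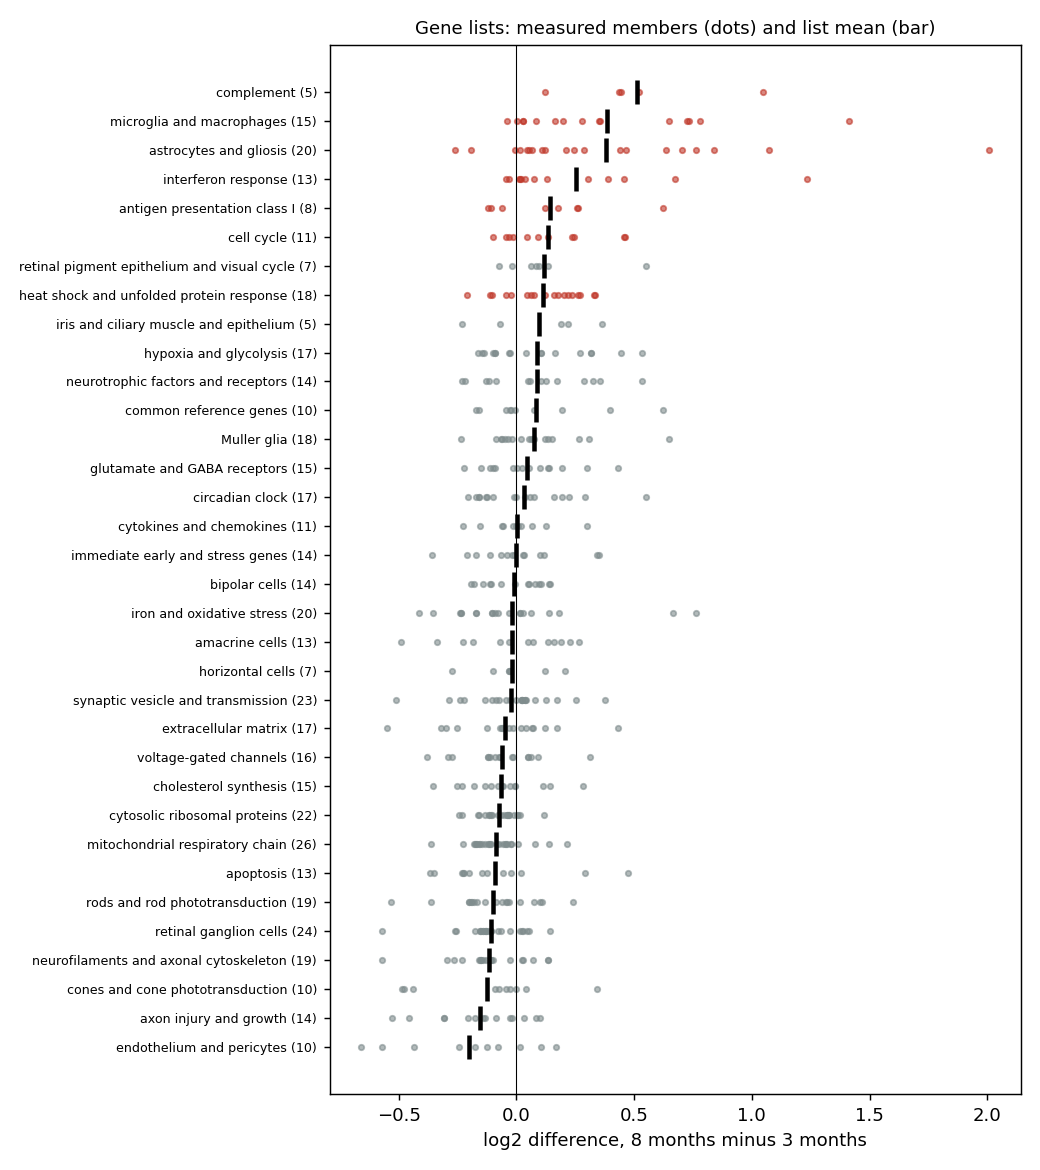
Log2 difference between 8 and 3 months (x axis) of each measured member (dots) of the tested gene lists (y axis, number of measured genes in brackets), with the list mean as a black bar; lists in red passed limma camera at an adjusted p of 0.05. The crystallin list is left out of the plot. The means of complement, microglia and gliosis lie at 0.51, 0.38 and 0.38.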

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

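The alternatives that use the crystallin level, or leave out the 2 crystallin-rich arrays, were chosen after the data were seen, and all others were planned. Where a call was lost or gained the cause was not tested. Leaving arrays out, adding a term or estimating the correlation in camera does leave fewer degrees of freedom. The count of probe sets past the threshold, 1 for all arrays, was 0 with no filter, 2 with the filter at 6, 2 after quantile normalization, 2 after cyclic loess, 3 with an intensity trend and robust prior, 0 with eye side as a covariate, 0 without the 2 crystallin-rich arrays and 2 at an adjusted p under 0.10. The count of genes, also 1, was 0, 2, 2, 2, 2, 0, 0 and 2 under the same settings and 2 with the mean of a gene's probe sets. Wherever 2 genes passed they were Glb1l3 and Csrp3. Leaving out 1 array at a time gave from 0 to 0 probe sets and from 0 to 0 genes. Glb1l3 had a limma adjusted p of 0.0694 to 0.164 over those fits, 0.156 with no filter, 0.416 with eye side and 0.664 without the 2 crystallin-rich arrays. Over the alternatives that keep its call the adjusted p lay between 0.00141 and 0.0318, and its log2 difference stayed between 1.94 and 2.12 throughout.

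At an unadjusted p under 0.05, limma gave 2059 probe sets with eye side as a covariate and 1567 without the 2 crystallin-rich arrays, against 3126, and 1932 to 4109 with 1 array left out, the lowest without 8-month retina 2.

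The replicate numbers do not pair the samples, since same-numbered arrays of both ages had deviations that correlated at -0.14, 0.06 and -0.28, and not every array correlated best with its own number. With the replicate block, 0 probe sets and 0 genes passed (Glb1l3, limma adjusted p = 0.336), 2728 probe sets had an unadjusted p under 0.05, and the same 7 lists passed.

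Of the 7 called lists, camera called 2 with the filter at 6 and 4 without the less specific probe sets. Complement had fewer than 5 measured genes under both settings, and interferon under the first, and so could not be tested there. Fry called 4 lists and camera with an estimated correlation 0. With the filter at 6 the limma camera adjusted p was 0.0848 for gliosis, 0.0523 for microglia and 0.0795 for cell cycle. With eye side it was 0.260 for class I, 0.134 for interferon, 0.144 for heat shock and 0.260 for cell cycle, while gliosis, microglia and complement passed. The crystallin list reversed there and passed as higher at 8 months (limma camera, adjusted p = 0.0213), because the 1 older left eye is a crystallin-rich retina. Without the less specific probe sets it was 0.0533 for class I and 0.159 for cell cycle. Cell cycle also lost its call with no filter (0.0814), after quantile normalization (0.0655), after cyclic loess (0.0845) and with the mean of a gene's probe sets (0.169). With an estimated correlation the adjusted p was 0.155 for gliosis, microglia and complement, 0.412 for class I, 0.333 for interferon, 0.520 for heat shock and 0.333 for cell cycle. By fry it was 0.0599 for gliosis, 0.197 for class I, 0.179 for interferon, 0.359 for heat shock and 0.223 for cell cycle. Leaving out 1 array gave 0.00558 to 0.216 for class I, highest without 3-month retina 2, and 0.00717 to 0.150 for cell cycle, highest without the same retina. The other 5 called lists passed in each of those 6 fits. With the crystallin level as a covariate 9 lists passed and without the 2 crystallin-rich arrays 8, the 7 among them each time.

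Some uncalled lists gained a call in limma camera. With no filter, respiratory chain and ribosomal proteins passed as lower (adjusted p = 0.00688 and 0.0366). The median log2 difference of all probe sets was -7.96e-04 there, against -0.041 with the filter. Neurotrophic factors passed as higher without 8-month retina 1 (0.0279), with the crystallin level (0.0468) and without the 2 crystallin-rich arrays (0.0241). Müller glia passed as higher without 3-month retina 3 (0.0397) and with the crystallin level (0.0333), hypoxia without 8-month retina 2 (0.00535) and common reference genes with eye side (0.0294). Crystallins passed as lower without 8-month retina 1 (0.0211). By fry, axon injury and endothelium passed as lower (0.0476 each).

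Genes and lists uncalled on both sides that changed sign were counted as keeping their side, 21 genes and 18 lists over the settings with all replicates or 2 arrays out, and 14 genes and 10 lists with 1 array left out. With no filter 45037 probe sets were tested, and whether values near the floor or the larger adjustment ended the call of Glb1l3 was not separated.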

Other observations

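Several genes measured by 3 or more probe sets differed in every one of them. Of 1708 such genes, 13 had all probe sets at an unadjusted limma p under 0.05 in 1 direction, 4 higher and 9 lower at 8 months. The RNA-binding protein gene Hnrnpa2b1 was higher by 0.30 to 0.43 on the log2 scale over 4 probe sets, and Xist, the long RNA of the inactive X chromosome, by 0.29 to 0.66 over 3 in these female mice. Tmem176a and 4632427E13Rik were the other higher genes, by 0.40 to 0.62 and by 0.48 to 0.88. The RNA helicase gene Ddx39a differed by -0.60 to -0.37 over 4 probe sets, and Apex1, a DNA repair endonuclease gene, by -0.64 to -0.38 over 3. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05, and 1 of them, that by age, gave 13 such genes, the highest other giving 4. These genes were picked after their values were seen, and none passed limma's adjustment over all probe sets.

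In what follows, the tests of lens material between ages, of eye side and of a lower share of neurons were chosen only after the results were seen, as was the fit with the crystallin level. Crystallins were far higher in 8-month retina 1 and 3-month retina 3, 1 retina of each age, and 10 of the 14 crystallin genes on the array had their highest values in those arrays. Of 8 lens genes that are no crystallins, 6 were highest in the same arrays, where 5.27% of probe sets are (exact one-sided binomial p = 5.48e-07). Lens tissue carried into the samples would give this pattern. The test takes the genes as independent, but genes of 1 tissue read in the same retinas can move together. Its p therefore does not measure the strength of the evidence across retinas. The lens membrane channel gene Mip read 8.33 and 10.64 there and 2.92 to 2.93 in the other arrays, and the connexin gene Gja3 8.49 and 9.27 against 2.24 to 2.32. Crystallin expression by the retina without lens tissue would leave these genes level, and their median log2 difference was 1.74 (quartiles 0.56 and 3.86). That comparison covers 8-month retina 1 and 3-month retina 3 only. In 3-month retina 1 some crystallins were also raised, with Cryba1 at 8.90 and Crybb2 at 7.24. There Mip and Gja3 stayed low, at 2.93 and 2.25, while Bfsp2 and Grifin, at 4.57 and 3.61, were above the remaining arrays. The source of crystallin in that retina was not tested. Cryab, at 10.12 to 10.42 in the other 4 arrays, is the 1 crystallin with a high level in all retinas, and no other biological explanation was tested, since the design names none for these retinas.

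Camera called the microglia, gliosis and complement lists as higher at 8 months with its preset correlation, and called none of them with an estimated correlation (limma adjusted p = 0.155 for each). Unequal lens material as the whole cause is argued against, because with the crystallin level as a covariate the 3 lists kept 1.02 to 1.05 times their mean shift. Eye side stays open, since the fit with it as a covariate, in which they kept 0.839 to 1.05 times their shift (limma camera, adjusted p = 1.07e-04 for microglia and 2.25e-04 for the others), compares 1 older left retina with the younger ones. A lower share of neurons would raise other cell types alike, yet the microglia shift exceeded that of endothelium by 0.583 (bootstrap 95% interval over genes 0.340 to 0.845) and that of Müller glia by 0.308 (0.101 to 0.532). These intervals measure the spread among genes and not among animals, so they do not settle the share of neurons. The endothelium list was itself lower at 8 months, with a mean of -0.20. RNA quality was not tested and stays open, since the 3' minus 5' signal of Gapdh was higher in all older retinas, and a rise of glial and immune cells, or of their transcripts, with age or pressure stays an untested hypothesis.

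The 10 splits of the arrays into 3 and 3 are too few for a share under 0.05. The split by age gave 1 probe set past the threshold against 0 in the highest other, 3126 at an unadjusted p under 0.05 against 1406, and 7 lists against 10, with 3 splits calling 7 or more. Of the 4 splits that put the crystallin-rich retinas in the same group, 2 called 10 and 7 lists and the others 2 and 4, and what made these calls was not tested. Microglia and gliosis each passed in 3 other splits and complement in 2, at larger p than by age, and class I passed in 0. Another split gave a smaller limma camera adjusted p than age did for heat shock (1.35e-04 against 6.79e-04), interferon (0.00196 against 0.00261) and cell cycle (0.0312 against 0.0353).

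Lcn2, Chil1 and Ifitm3 lay near the 3-month level in 8-month retina 1, with Chil1, a chitinase-like secreted protein gene, at 7.14 against 9.28 and 9.12 in the other older retinas. Ifitm1 and Ly86 did likewise, at 4.84 against 6.88 and 6.28 and at 4.60 against 6.23 and 5.75; Chil1, Ifitm1 and Ly86 were picked after their values were seen. Dilution by lens RNA would lower retinal genes alike, but rod genes differed by a median of -0.00523 (SD 0.129 over genes) in that retina against -2.06 for the 3 genes. A 3-month sample under an 8-month label would lie near the younger level, but over the 100 probe sets that best part the other arrays by age it lay a median of 0.815 of the way to the older level (quartiles 0.412 and 1.04). A weaker reaction in that eye, whose pressure of 25.3 mmHg was the lowest of the 3, and its left side both stay open with 1 retina. Among the older retinas its mean shift was the lowest for interferon (0.11), gliosis (0.32), class I (0.09), heat shock (0.045) and cell cycle (0.11). It lay between the others for microglia (0.39) and was the highest for complement (0.54), with C1qb lowest at 7.65 and Lyz1 highest at 6.11.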
